A study of Mus musculus with 6 samples.

How the data were processed

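The 6 libraries of the series were used, 3 of macrophages grown from LFA1-lo Itgam-lo monocytes and 3 from LFA1-hi Itgam-hi monocytes of mouse bone marrow. Per the labels, cells were cultured for 7 days in medium with 10% serum and 20 ng/ml M-CSF, which was refreshed on day 4. RNA was purified on small columns, ribosomal RNA was depleted enzymatically, and libraries were read on a NextSeq2000, per the labels' protocols. The submitters' processing notes name bcl2fastq, Trim Galore and RSEM and the genome build GRCm38. Their versions, the aligner, the annotation release and the use of the read strand are not given in the sources used here.

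The deposited files hold gene-level RSEM output for 24411 genes on RefSeq transcripts. Per the file headers they give expected counts, the estimated number of reads or fragments of each gene, which were not normalized. The deposited TPM values are, per the file headers, transcripts per unit of library after division by effective length, and they summed to 1000000 or 999999 in each file. The deposited FPKM values are, per the file headers, fragments scaled by effective length and library size. Genes were matched to RefSeq by transcript accession (24161) or by symbol (157), and 93 had no match. Coordinates are from GRCm38, counted from 1.

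Expected counts were rounded, since 5.53% to 6.06% of genes in a library had a count that was not whole. Genes were filtered with filterByExpr, which left 11692, and libraries were scaled by TMM (factors 0.956 to 1.034). The LFA1-hi minus LFA1-lo difference was tested with robust quasi-likelihood fits in edgeR 4.0.16 on R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Both groups shared an estimate of the spread (biological coefficient of variation 15%). Standard errors and 95% intervals come from the same fit. Means and SDs are of CPM over the 3 libraries of a group, and PCA used log2 CPM (prior count 2) of the 500 most variable genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

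Before the data were examined, 42 gene lists were fixed, covering cell types, immune functions, metabolism and the cell cycle. The 37 with at least 3 tested members were tested 2-sided with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and besides with the correlation estimated from the data. Camera asks whether a list moved relative to the other genes, and fry, run beside it, whether it moved at all, so fry answers another question, and ranges over alternatives for lists include its p. Each list's p was adjusted over these 37. Genes named in the text follow a rule fixed at the same time. It takes Itgam, Itgal and Itgb2, then the 12 largest changes each way among called genes with mean CPM of at least 1 and no overlap between the groups, then up to 4 called members of each list with the largest changes. Genes outside this rule are marked as chosen after their values were seen. Some genes that the rule takes are not reported here. Of 173 genes counted, some taken by the rule and others chosen after their values were seen, 167 passed the threshold, and 29 overlap another annotated gene.

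A gene with 0 counts in a group is given as at least the fold that 3 counts over the group would allow, and a gene with 1 to 3 counts as a ratio with its counting interval, which covers counting error only. No list's median moved when such genes were placed at these bounds. Genes with near-identical copies, such as histones, class I heavy chains, Raet1 and ribosomal protein genes, and genes that overlap others are uncertain, as reads can be assigned to either.

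Data were simulated from the mean counts of these libraries, with a spread for each gene shared by both groups, and the filter left 11571 genes. The real LFA1-lo libraries varied more than the LFA1-hi libraries, which was not simulated. On these data the procedure recovered 25 of 100 genes changed by 1.5-fold and 73 of 100 changed by 2-fold, with 8 false calls among 106. A planted list passed in camera with the preset correlation (adjusted p = 4.51e-201) and 0 of the other lists did. Genes were simulated independently of one another, so this cannot tell how the set test behaves with correlated genes. Alternatives were other scalings (RLE, upper quartile, library totals), no filter or at least 10 CPM in 3 libraries, unrounded counts, leaving out each library, a block for the replicate number, and leaving out ribosomal and other small RNA genes. Others were DESeq2 1.42.0, limma voom, limma-trend on log2 of TPM + 0.1, TPM + 1 or FPKM + 0.1, a threshold of 0.01, a test against a 1.5-fold change, and fits that are not robust. Counts of list members without each library, and removal of trends over GC content and length, were added after seeing the data.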

Results

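Gene expression was measured by RNA sequencing in macrophages grown from bone marrow monocytes of C57BL/6 mice, an inbred laboratory strain. Monocytes had been sorted with a fluorescence-activated cell sorter into a subset low for both LFA1 and Itgam and a subset high for both. Each was then kept for 7 days with macrophage colony-stimulating factor (M-CSF), the growth factor that drives monocytes to become macrophages. LFA1 is a leukocyte adhesion receptor made of the chains encoded by Itgal and Itgb2. Itgam, also called CD11b, encodes a chain that pairs with the Itgb2 product in another adhesion receptor. The series held 3 libraries from each subset, called LFA1-lo and LFA1-hi macrophages here after the sort that preceded the culture.

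Summed expected counts were 17020599, 16404922 and 17115544 in LFA1-lo replicates 1, 2 and 3, and 17614509, 15191262 and 17597781 in LFA1-hi replicates 1, 2 and 3. Between 13248 and 13585 of the 24411 listed genes had a count above 0 in a library. A count of 3 corresponded to 0.170 to 0.198 CPM (counts scaled to a library total of 1000000). Rn45s, the precursor of ribosomal RNA, took 4.89% ± 0.524 of the counts in LFA1-lo and 5.86% ± 0.130 in LFA1-hi libraries (mean ± SD, n = 3 each). The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

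The labels imply a single comparison, how macrophages grown from the LFA1-hi monocytes differ from those grown from the LFA1-lo monocytes after the same culture. Of the genes of S phase 27 of 28 rose in LFA1-hi macrophages, as did 30 of 30 of G2 and M phase and 27 of 28 for histones. Of immediate early genes 14 of 22 fell, as did 7 of 11 of class II and 8 of 15 of class I antigen presentation, 12 of 32 of the lysosome and 16 of 26 of macrophage identity. These lists passed camera's set test with a preset correlation but not with an estimated correlation (adjusted p = 0.157 for S phase, 0.287 for class II, 0.399 for class I and 0.253 for the others, each with an estimated correlation). In all, 3705 of 11692 tested genes (31.7%) passed a false discovery rate of 0.05, 1883 of them higher and 1822 lower in LFA1-hi, and 622 and 445 of these differed by at least 2-fold. The higher share of calls, 50.8%, became 60.9% when libraries were scaled by their totals alone (2294 higher, 1471 lower) and 64.1% on log2(FPKM + 0.1) (2346 higher, 1316 lower). For 4844 genes (41.4%) the 95% interval of the fold change lay within 1.5-fold in both directions. Values of the 6 libraries did not overlap between the groups for 5586 tested genes (47.8%), where chance gives 10%. Leaving out LFA1-hi replicate 1, 2 or 3 lowered the count of genes to 2342, 2288 or 2427. Without LFA1-lo replicate 1 or 3 it was 2737 or 3510, but without LFA1-lo replicate 2 it rose to 5032.

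The first principal component of the 500 most variable genes held 69.5% of the variance and separated the groups, with scores of −32.1 to −21.22 in LFA1-lo and 23.52 to 27.13 in LFA1-hi libraries. The second held 10.6% and spread the LFA1-lo libraries, from −17.08 in replicate 2 to 16.07 in replicate 1, more than the LFA1-hi libraries (−5.1 to 3.31). LFA1-lo replicate 2 thus stood apart from the other LFA1-lo libraries, and counts without it are given below wherever they moved by over 1.5-fold. Pearson correlations of log CPM were 0.969 to 0.979 within LFA1-lo, 0.984 to 0.988 within LFA1-hi and 0.934 to 0.952 between the groups.

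**Figure D1:**
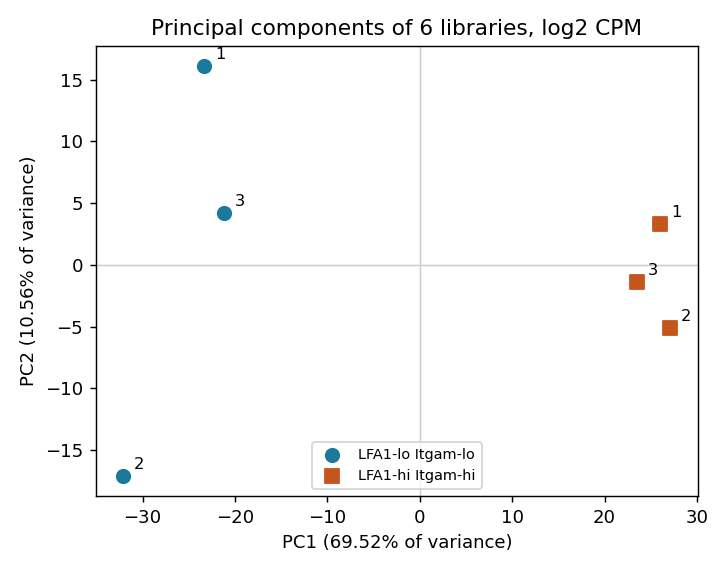
Principal component scores of the 6 libraries from log2 CPM of the 500 most variable genes, circles for LFA1-lo and squares for LFA1-hi. The horizontal axis (69.5% of the variance) parts the groups, and the vertical axis (10.6%) spreads the LFA1-lo libraries between −17.08 and 16.07.

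The genes of the sort markers did not pass the test after the 7 days of culture. Itgam (GRCm38 chromosome 7, 128062640 to 128118491) stood at 1262 ± 98.0 CPM in LFA1-lo and 1211 ± 83.8 CPM in LFA1-hi (n = 3 each; log2 fold change −0.06, SE 0.09, edgeR adjusted p = 0.646). Itgal (chromosome 7, 127296139 to 127335137) was at 122 ± 50.1 CPM, with 145, 64.3 and 156 CPM in the LFA1-lo libraries, and at 205 ± 10.2 CPM in LFA1-hi (log2 fold change 0.75, SE 0.30, adjusted p = 0.0997). Without LFA1-lo replicate 2 its value was 0.45 (adjusted p = 0.000143), and with limma voom 0.85 (adjusted p = 0.0422), against a range over alternatives of 0.000143 to 0.235. Itgb2 (chromosome 10, 77530329 to 77565708) was at 1421 ± 419 and 1154 ± 80.3 CPM (log2 fold change −0.30, SE 0.19, adjusted p = 0.273). It passed without LFA1-lo replicate 3 (−0.48, adjusted p = 0.0259, the lowest over alternatives that reached 0.739). Over the fits without a library its log2 fold change ran from −0.48 to −0.05.

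Among the 12 largest rises, Fabp7, a fatty acid binding protein (chromosome 10, 57784923 to 57788450), went from 0.778 ± 0.547 CPM in LFA1-lo to 30.9 ± 8.04 CPM in LFA1-hi (log2 fold change 5.28, SE 0.38, edgeR adjusted p = 4.87e-05), and its value was 6.04 without LFA1-lo replicate 3. Cd300e, an activating receptor of myeloid cells, rose from 1.46 ± 0.547 to 15.0 ± 3.62 CPM (3.34, SE 0.31, adjusted p = 0.000101). Raet1d, which encodes a ligand of the killer cell receptor NKG2D, rose from 2.10 ± 0.171 to 21.1 ± 3.72 CPM (3.32, SE 0.20, adjusted p = 1.42e-05), though its reads can be shared with close Raet1 copies. Slfn4 (4.52), Dnmt3l (3.94) and Ccl12 (3.43), a monocyte chemoattractant, were low in both groups. Among the 12 largest falls, Il4i1, an enzyme that breaks down phenylalanine, had 315 counts over the LFA1-lo libraries and 0 in LFA1-hi, at least 109-fold lower (at least 71.3-fold without LFA1-hi replicate 1 or 3). Tmem176b (chromosome 6, 48833811 to 48845948), a membrane protein of the immature dendritic cell and macrophage, fell from 88.6 ± 43.5 to 2.58 ± 0.768 CPM (−5.11, SE 0.42, adjusted p = 0.000229), and the gene Tmem176a inside its span fell with it (−5.81, or −5.17 without LFA1-lo replicate 2), although reads of overlapping genes may be assigned to either. Col4a6, a basement membrane collagen, had 137 counts against 1 (ratio 143, 95% counting interval 25.2 to 5670). That count lay in LFA1-hi replicate 1, without which Col4a6 was at least 31.0-fold lower, and without LFA1-hi replicate 3 the ratio was 93.1.

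**Figure D2:**
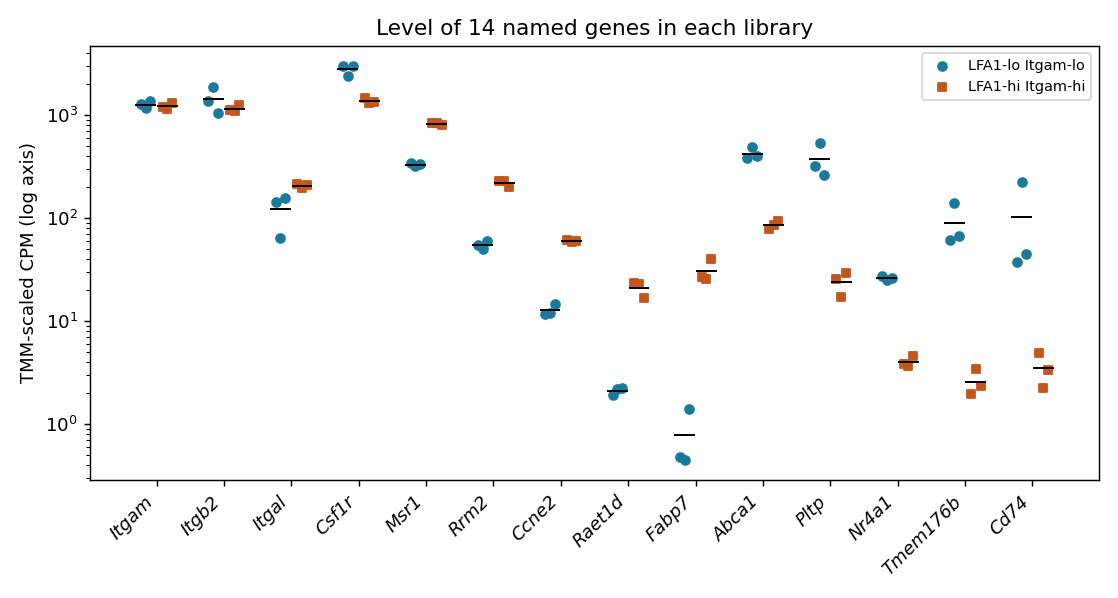
CPM (log axis) of 14 genes in each library, circles for LFA1-lo, squares for LFA1-hi, bars at the group means. Itgam stands at 1262 and 1211 CPM, Rrm2 at 55.2 and 219.9 CPM and Abca1 at 423 and 85.8 CPM in LFA1-lo and LFA1-hi, and Cd74 varies from 37.8 to 224 CPM among the LFA1-lo libraries.

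Genes that act in the dividing cell were higher in LFA1-hi macrophages. Of 28 tested S phase genes 27 rose (median log2 fold change 1.52), among them Rrm2, a subunit of the enzyme that makes deoxynucleotides (55.2 ± 5.08 to 219.9 ± 15.7 CPM, n = 3 each; log2 fold change 1.99, SE 0.10, edgeR adjusted p = 9.81e-06). Ccne2, encoding cyclin E2, rose by 2.22 (adjusted p = 9.81e-06). All 30 genes of G2 and M phase rose (median 1.49), such as Bub1, a kinase of the spindle checkpoint (1.73, adjusted p = 4.77e-05), Ccnb1, encoding cyclin B1 (1.73, adjusted p = 0.00279), and Birc5, or survivin (1.75, adjusted p = 0.000178). Of 28 replication-dependent histone genes 27 rose (median 1.41), including Hist1h3a (2.08) and the linker histone gene Hist1h1a (1.80). Their summed level went from 1529 to 3829 CPM, that of the S phase genes from 1333 to 3006 CPM and that of the G2 and M phase genes from 1250 to 3448 CPM. Single histone genes are uncertain, since near-identical copies share reads. The S phase gene that did not pass was Pcna, the sliding clamp of DNA polymerase, singled out after its values were seen, at 429.9 ± 142 and 511 ± 14.1 CPM (0.25, adjusted p = 0.396). Without LFA1-lo replicate 2 it passed (0.55, adjusted p = 1.26e-05, where alternatives ran up to 0.747).

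In camera's set test the 3 lists passed with adjusted p = 1.92e-54 for S phase, 6.41e-25 for G2 and M phase and 3.55e-34 for histones. These calls were lost when the correlation between genes was estimated. For S phase, adjusted p = 0.157 with an estimated correlation, the highest over alternatives that began at 5.34e-67. For G2 and M phase, adjusted p = 0.253 with an estimated correlation (from 2.19e-51), and for histones adjusted p = 0.253 with an estimated correlation (from 3.22e-60). Over the 6 fits without a library, 27 or 28 S phase, 26 to 30 G2 and M phase and 26 or 27 histone genes passed the threshold.

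Targets of the tumour suppressor p53 were higher as a list in LFA1-hi macrophages, with 10 of 19 rising and 1 falling (median 0.50). The largest rises were of Ckap2 (1.63) and Gtse1 (1.57), which also act on the mitotic spindle, and of Phlda3, an inhibitor of Akt signalling (1.28, SE 0.17, edgeR adjusted p = 0.000558). Cdkn1a, the cell cycle inhibitor p21, and Mdm2, the ligase that degrades p53, both chosen after their values were seen, rose by 0.74 each (adjusted p = 0.000189 and 0.000921). Sesn1 fell (−0.96, adjusted p = 0.014), a call narrowly missed without LFA1-hi replicate 2 (−0.94, adjusted p = 0.0502, the highest over alternatives from 1.36e-07). The falling members numbered 3 without LFA1-lo replicate 2 and 2 without LFA1-lo replicate 3. Camera gave this list adjusted p = 0.0018, and adjusted p = 0.268 with an estimated correlation, the highest over alternatives from 0.00048.

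Nuclear genes of oxidative phosphorylation rose in 12 of 31 cases (14 adjusted over the list alone), with a median of 0.20. Cycs, encoding cytochrome c, rose from 60.0 ± 19.2 to 117 ± 3.42 CPM (0.97, SE 0.20, edgeR adjusted p = 0.00846), Cox7a2 by 0.64 and Atp5b, a subunit of ATP synthase, by 0.46. The count was 5 without LFA1-lo replicate 1, LFA1-hi replicate 1 or LFA1-hi replicate 3 and 7 without LFA1-hi replicate 2, and 1 member fell without LFA1-lo replicate 2. As a list they had camera adjusted p = 0.00749, and adjusted p = 0.399 with an estimated correlation (alternatives from 0.000194). Of 24 genes of glycolysis and hypoxia 8 rose and 1 fell (10 and 2 adjusted over the list alone), and the list did not pass (median 0.20, adjusted p = 0.147). Pfkfb3, which makes the activator of phosphofructokinase, rose by 0.73 and Vegfa, a hypoxia-induced growth factor, fell by 1.93 on the log2 scale. Rising members numbered 15 without LFA1-lo replicate 2, where the list passed (adjusted p = 1.79e-05, range over alternatives 1.79e-05 to 0.868). They numbered 1 without LFA1-lo replicate 1, 4 without LFA1-hi replicate 2 and 2 without LFA1-hi replicate 1 or 3, and falling members 2 and 3 without LFA1-lo replicates 2 and 3.

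Genes that define macrophages were lower in LFA1-hi cultures, where 16 of 26 fell (17 adjusted over the list alone) and 3 rose (median −0.41). Csf1r, the receptor for M-CSF, fell from 2790 ± 343 to 1374 ± 84.7 CPM (n = 3 each; −1.02, SE 0.10, edgeR adjusted p = 0.000155). Apoe, a lipid carrier protein (−0.93, adjusted p = 0.00453), and Cd14, a coreceptor for bacterial lipopolysaccharide (−0.86, adjusted p = 0.000489), also fell. Siglec1, a sialic acid receptor of macrophages, rose from 251 ± 38.8 to 506 ± 16.8 CPM (1.01, SE 0.11, adjusted p = 0.000242). Adgre1, the F4/80 antigen, named after its values were seen, fell by 0.83 on the log2 scale. Falling members numbered 10 without LFA1-hi replicate 2, and rising members 1 without any of the LFA1-hi libraries. In camera the list had adjusted p = 0.000409, and adjusted p = 0.253 with an estimated correlation (alternatives from 1.79e-05).

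Of 32 lysosomal genes 12 fell and 2 rose (median −0.19), and 20 fell without LFA1-lo replicate 2. Mitf (−1.30, SE 0.14, edgeR adjusted p = 0.000299) and Tfeb (−0.84, adjusted p = 0.000877), transcription factors that drive lysosomal genes, fell, as did Man2b1, a lysosomal mannosidase (−0.91), and Atp6v0a1, a subunit of the lysosomal proton pump (−0.87). The list had camera adjusted p = 0.00106, and adjusted p = 0.253 with an estimated correlation (alternatives from 0.000125). Among targets of the liver X receptor and genes of lipid export 8 of 18 fell and 3 rose (4 adjusted over the list alone), with a median of −0.34. Abca1, which exports cholesterol to apolipoproteins, fell from 423 ± 59.9 to 85.8 ± 8.12 CPM (−2.30, SE 0.12, adjusted p = 9.81e-06). Pltp, a phospholipid transfer protein, fell from 373 ± 146 to 24.1 ± 6.21 CPM (−3.95, adjusted p = 0.000243) and Abcg1, another cholesterol exporter, by 1.56 on the log2 scale, while the fatty acid carrier gene Fabp4 rose by 1.30. Falling members numbered 5 without LFA1-hi replicate 2. This list had camera adjusted p = 0.013, and adjusted p = 0.253 with an estimated correlation (alternatives from 0.00226), and it was also lost with limma voom and on TPM or FPKM. In cholesterol synthesis 2 of 22 genes rose and 1 fell (adjusted over the list alone, 1 fell), with adjusted p = 0.601. Of this list 11 fell without LFA1-lo replicate 2, the rising genes did not pass without LFA1-lo replicate 1 or any LFA1-hi library, 1 rose without LFA1-lo replicate 3, and none fell without LFA1-hi replicate 2.

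Complement genes were lower as a list, with 6 of 12 falling and 1 rising (median −0.48). C3, the central complement component, fell from 162 ± 60.5 to 7.25 ± 5.09 CPM (−4.47, SE 0.54, edgeR adjusted p = 0.00215; −5.22 without LFA1-hi replicate 1). Cfp, or properdin, fell by 0.67 on the log2 scale, whereas C1ra, a protease of the first component, rose by 1.21. Camera gave this list adjusted p = 0.00986, and adjusted p = 0.253 with an estimated correlation (alternatives from 0.000374), and was lost on TPM or FPKM (medians −0.31 to −0.20). Of 24 receptors of phagocytosis 4 rose, and the list did not pass (median −0.10, although camera's direction was up, adjusted p = 0.621). Msr1, a scavenger receptor, rose from 330.1 ± 10.5 to 818 ± 22.3 CPM (1.31, SE 0.07, adjusted p = 9.81e-06) and Cd300lf, a receptor for phosphatidylserine, by 1.51. The rising members numbered 2 without any LFA1-hi library, and 9 members fell without LFA1-lo replicate 2 and 1 without LFA1-hi replicate 2.

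Immediate early genes, which respond to growth factors and adhesion within minutes to hours, were lower in LFA1-hi macrophages. Of 22 tested, 14 fell and 3 rose (median −0.97), and 14 fell in each fit without a library, with 1 rising without LFA1-hi replicate 1 or 2. The nuclear receptor gene Nr4a1 fell from 26.1 ± 1.23 to 4.01 ± 0.458 CPM (n = 3 each; −2.70, SE 0.15, edgeR adjusted p = 9.81e-06). Egr1 (−2.50, adjusted p = 0.000152) and Egr3 (−4.27, adjusted p = 5.32e-05), zinc finger transcription factors, fell too. Nr4a3 had 50 counts over the LFA1-lo libraries and 0 in LFA1-hi, at least 17.3-fold lower (at least 11.3-fold without LFA1-hi replicate 1 or 3). As a list they had camera adjusted p = 2.7e-09, and adjusted p = 0.253 with an estimated correlation (alternatives from 2.21e-13).

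Inflammatory cytokines and targets of the transcription factor NF-kB were lower as a list, with 7 of 18 falling (10 adjusted over the list alone) and 1 rising (median −0.68). Cd86, a costimulatory molecule for T cells, fell from 24.1 ± 3.34 to 4.995 ± 0.533 CPM (−2.27, SE 0.17, edgeR adjusted p = 3.05e-05). Il1b, encoding interleukin-1 beta, fell from 4.10 ± 2.08 to 0.120 ± 0.104 CPM (−5.04, SE 0.72, adjusted p = 0.000912), and Socs3, an inhibitor of cytokine signalling, by 1.99 on the log2 scale. Rising members numbered 2 without LFA1-lo replicate 2, and none passed without LFA1-hi replicate 1 or 2. In camera the list had adjusted p = 0.00133, and adjusted p = 0.253 with an estimated correlation (alternatives from 0.000152). Of 23 pattern recognition receptors 8 fell and 2 rose (median −0.21; 1 rose without LFA1-hi replicate 2). Clec4n, or dectin-2, a receptor for fungal sugars (−2.60, SE 0.19, adjusted p = 3.7e-05), Tlr9, which senses bacterial DNA (−2.35, adjusted p = 4.77e-05), and Tlr2, a receptor for lipoproteins (−1.81, adjusted p = 0.000142), fell. Mb21d1, the DNA sensor cGAS, rose by 1.02. This list had camera adjusted p = 0.0054, and adjusted p = 0.253 with an estimated correlation (alternatives from 0.000763), and was lost on log2(TPM + 0.1).

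The type I interferon response was lower as a list, with 12 of 30 genes falling (13 adjusted over the list alone; median −0.63), but this count varied widely with the libraries and the filter (6 fell without a filter). Isg15, a ubiquitin-like modifier induced by interferon, fell from 18.3 ± 9.90 to 4.90 ± 0.689 CPM (−1.89, SE 0.40, edgeR adjusted p = 0.00952). Ifit3, an interferon-induced antiviral gene, fell by 2.60 on the log2 scale, a call lost without LFA1-lo replicate 2 (−2.14, adjusted p = 0.0587) or LFA1-lo replicate 3 (−2.55, adjusted p = 0.0544), over alternatives of 8.17e-05 to 0.0612. Falling members numbered 23, 4 and 6 without LFA1-lo replicates 1, 2 and 3, and 7 and 5 without LFA1-hi replicates 2 and 3, and 2 rose without LFA1-lo replicate 2. The list had camera adjusted p = 0.0018, and adjusted p = 0.659 with an estimated correlation, the highest over alternatives from 3.1e-18. It was also lost without LFA1-lo replicate 2 (adjusted p = 0.0777), and fry, which tests the list against no change and not against other genes, gave adjusted p = 0.214.

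Genes of class II antigen presentation were lower in LFA1-hi macrophages, with 7 of 11 falling and 2 rising (median −2.27). The list also holds costimulatory genes. Cd86 (−2.27), given above with the inflammatory genes, is among the falling members and its value equals the median. Ciita, the master regulator of class II genes, had 46 counts over the LFA1-lo libraries and 0 in LFA1-hi, at least 16-fold lower (at least 10.4-fold without LFA1-hi replicate 1 or 3), a call lost on log2(TPM + 1) (adjusted p = 0.0875, the highest over alternatives from 7.84e-05). H2-Aa, a class II alpha chain, fell from 11.9 ± 13.3 to 0.250 ± 0.123 CPM (n = 3 each; −5.51, SE 1.06, edgeR adjusted p = 0.00786), with 3.88, 27.2 and 4.58 CPM in LFA1-lo replicates 1, 2 and 3, and its value was −4.03 without LFA1-lo replicate 2, and it did not pass with limma voom (adjusted p = 0.0676, the highest over alternatives from 1.21e-06). Cd74, the invariant chain, was at 37.8, 224 and 44.9 CPM in the LFA1-lo libraries and at 3.50 ± 1.35 CPM in LFA1-hi (−4.85, adjusted p = 0.0231; −3.55 without LFA1-lo replicate 2). Its call was lost without LFA1-hi replicate 2 (−4.61, adjusted p = 0.0634) or 3 (−4.81, adjusted p = 0.0806, the highest over alternatives from 2.18e-07). H2-Eb1, a class II beta chain, had 342 counts against 2 (ratio 178, 95% counting interval 48.9 to 1480) and 0.895, 18.2 and 2.47 CPM in the LFA1-lo libraries. The ratio was 43.4 without LFA1-lo replicate 2 and 116 without LFA1-hi replicate 1, and at least 77.4 without LFA1-hi replicate 3. The H2-Eb1 call was lost without LFA1-hi replicate 1, 2 or 3 (adjusted p = 0.0512, 0.0639 and 0.097, over alternatives of 0.000502 to 0.097). The rising members, H2-DMb1, a chaperone of peptide loading (0.43), and Cd40, a costimulatory receptor (0.81), were named after their values were seen. The median rests on scarce members, as the 10 CPM filter left 7, of which 3 fell and 2 rose (median −0.14), and 5 of 14 fell without a filter and 4 of 11 with limma voom. Neither H2-DMb1 nor Cd40 passed without LFA1-hi replicate 1 or 2, and 1 did without LFA1-hi replicate 3, while 4 members fell without LFA1-hi replicate 2 or 3. Camera gave this list adjusted p = 0.000361, and adjusted p = 0.287 with an estimated correlation (alternatives from 1.02e-05).

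Of 15 genes of class I antigen presentation 8 fell (median −0.38; 5 without LFA1-hi replicate 1), and 2 rose without LFA1-lo replicate 2. Tapbp, or tapasin, which loads peptides onto class I molecules (−0.998, SE 0.11, edgeR adjusted p = 0.000242), B2m, their shared light chain (−0.87, adjusted p = 0.000789), and the heavy chain genes H2-D1 (1591 ± 166 to 860.3 ± 37.3 CPM, −0.89) and H2-K1 (−0.83) fell, though these heavy chain genes can share reads with related copies. As a list they had camera adjusted p = 0.00133, and adjusted p = 0.399 with an estimated correlation (alternatives from 0.000152). Of 5 tested dendritic cell markers 2 fell, Ccl22, a T cell attracting chemokine (−4.98, or −4.31 without LFA1-lo replicate 2), and Tcf4, a transcription factor of plasmacytoid dendritic cells (−0.79). This list did not pass in camera (median −0.58, adjusted p = 0.144) but did with fry (0.00723, range over alternatives 0.00723 to 0.348), and 4 of 8 then tested fell without LFA1-lo replicate 2 (median −0.33). The median was −0.001 without LFA1-lo replicate 3 and −0.35 without LFA1-hi replicate 1 (7 and 8 tested).

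Markers of neutrophils and their granules were lower as a list in LFA1-hi macrophages, with 4 of 7 falling and 1 rising (median −1.28, or −2.42 without LFA1-hi replicate 2). The most abundant members, named after their values were seen, were Mmp8, a collagenase (102 ± 46.6 and 94.3 ± 12.7 CPM, edgeR adjusted p = 0.837), and Csf3r, the receptor for granulocyte colony-stimulating factor, which fell from 54.5 ± 4.94 to 22.5 ± 3.04 CPM (adjusted p = 0.000131). The 10 CPM filter left these 2 members, with a median of −0.70. S100a9, a calcium-binding protein of neutrophils and monocytes, fell from 9.61 ± 5.45 to 0.556 ± 0.154 CPM (−4.08, SE 0.57, edgeR adjusted p = 0.00117), and Ngp, a granule protein, by 4.19 on the log2 scale (−4.81 without LFA1-hi replicate 3). Cebpe, a transcription factor of late granulocyte development, rose by 3.17 (edgeR adjusted p = 0.00174). It went from 0.202 ± 0.029 CPM in LFA1-lo, near the level of a count of 3, to 1.885 ± 0.416 CPM in LFA1-hi. In camera the list had adjusted p = 0.0205, and adjusted p = 0.253 with an estimated correlation (alternatives from 1.44e-05). It was lost without LFA1-lo replicate 3 (adjusted p = 0.0549), with limma voom and on TPM or FPKM. Of 6 stem and progenitor genes 3 fell and 1 rose (median −1.37, camera adjusted p = 0.174, fry 0.012, range over alternatives 0.012 to 0.385), among them Sox4, a progenitor transcription factor (−2.14, adjusted p = 0.000342). The rising gene, Ly6a (0.89), did not pass without LFA1-lo replicate 1 or LFA1-hi replicate 1 or 2, and 1 fell without LFA1-hi replicate 3. Of 5 megakaryocyte genes 2 fell (1 without any LFA1-hi library; camera adjusted p = 0.174, fry 0.0099, range over alternatives 0.0099 to 0.541), such as Vwf, encoding von Willebrand factor (−0.94). In the B lymphocyte list (3 tested, adjusted p = 0.875) the receptor gene Cd22 rose by 1.16 and the adaptor gene Blnk fell by 0.75 on the log2 scale.

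None of 4 stromal and endothelial genes passed in edgeR (median 0.93, list adjusted p = 0.18 in camera and 0.023 with fry, range over alternatives 0.023 to 0.883), while 2 had an unadjusted p under 0.05, 2 passed adjusted over the list alone, 2 with DESeq2, 1 with limma voom and 2 in edgeR without LFA1-lo replicate 3. In edgeR 1 passed with library totals alone and 1 without a filter, where 13 members had a median of −0.46. Lists with fewer than 3 tested members had no set test. Of the T and natural killer cell markers Cd4, a coreceptor also found on myeloid cells, fell (−4.80, SE 0.53, edgeR adjusted p = 0.000229), and of the erythroid markers Tfrc, the transferrin receptor that brings iron into cells, rose from 158 ± 27.1 to 357 ± 36.1 CPM (1.18, adjusted p = 0.000254). Without LFA1-lo replicate 3 another erythroid marker passed and was lower. Of the mast cell, basophil and eosinophil markers Ccr3, a chemokine receptor, fell by 1.51 on the log2 scale and Siglecf, a sialic acid receptor, rose by 1.497. The Siglecf call was lost without LFA1-lo replicate 1 or 3 or LFA1-hi replicate 2 or 3 (1.41, 1.54, 1.498 and 1.14, adjusted p = 0.0903, 0.0576, 0.0946 and 0.167, over alternatives of 0.0124 to 0.167). Xist, the transcript that silences an X chromosome in females, fell from 799 ± 75.02 to 563 ± 94.1 CPM (−0.50, adjusted p = 0.0144), and its call was lost without LFA1-hi replicate 1 or 3 (−0.38 and −0.51, adjusted p = 0.0543 and 0.0553, over alternatives of 0.00133 to 0.0553), and its reads cannot be told from those of its antisense partner Tsix. The 4 Y-linked genes had 0 counts in every library. Mitochondrially encoded transcripts were not analysed here.

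Monocyte genes moved in both directions, with 6 of 16 rising and 6 falling (median −0.28, adjusted p = 0.266). Ccr2, the receptor that draws monocytes out of the bone marrow, fell from 31.7 ± 11.8 to 3.01 ± 0.498 CPM (−3.40, SE 0.31, edgeR adjusted p = 0.000169), and Hp, encoding haptoglobin, by 2.67 on the log2 scale. Cx3cr1, the fractalkine receptor of patrolling monocytes, rose from 22.7 ± 10.6 to 62.8 ± 7.83 CPM (1.47, adjusted p = 0.0132), and without LFA1-lo replicate 3 the call was lost at a similar value (1.46, adjusted p = 0.0621, the highest over alternatives from 2.19e-06). Treml4, a receptor of nonclassical monocytes named after its values were seen, rose by 1.79. Nr4a1, also a member of this list, fell from 26.1 ± 1.23 to 4.01 ± 0.458 CPM (−2.70, adjusted p = 9.81e-06). Without LFA1-lo replicate 1 the list passed (adjusted p = 0.0417), as it did with fry (0.0351, range over alternatives 0.0351 to 0.768). Of 11 chemokine receptors 2 rose and 3 fell (median 0.09, adjusted p = 0.408), among them Cxcr4, which holds cells in the bone marrow (−1.82, adjusted p = 0.00115), and 1 rose without LFA1-lo replicate 1 or any LFA1-hi library. Of 15 chemokines 4 rose and 7 fell (median −0.004, mean −0.66, camera's direction up, adjusted p = 0.842). The median was −0.65 and −0.20 without LFA1-lo replicates 1 and 3, −0.02 without LFA1-lo replicate 2, and −0.59, −0.51 and −0.49 without LFA1-hi replicates 1, 2 and 3 (15 or 16 tested). It was −1.03 over 19 members without a filter, and 6 rose without LFA1-lo replicate 2. Cxcl10, an interferon-induced chemokine, fell by 3.31 on the log2 scale (−2.65 without LFA1-lo replicate 2). Ccl2 and Ccl7, monocyte chemoattractants named after their values were seen, rose from 52.7 ± 10.7 to 204 ± 15.4 CPM (1.95, adjusted p = 3.05e-05) and from 14.3 ± 2.68 to 100.1 ± 9.56 CPM (2.81, adjusted p = 9.81e-06).

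Myeloid transcription factors were lower as a list, with 18 of 40 falling and 7 rising (median −0.28). Id1, an inhibitor of helix-loop-helix factors, rose from 7.48 ± 1.57 to 46.1 ± 2.62 CPM (2.62, SE 0.16, edgeR adjusted p = 1.42e-05), against the falls of Nr4a1 (−2.70) and Egr1 (−2.50), which also belong to the immediate early list. The list had camera adjusted p = 0.0205, and adjusted p = 0.268 with an estimated correlation (alternatives from 0.00447), and it was lost without LFA1-hi replicate 2 (adjusted p = 0.0508) and on TPM. Of 16 growth and angiogenic factors 8 fell and 1 rose (2 rose adjusted over the list alone; median −0.34). Csf1, which encodes M-CSF itself, fell from 28.8 ± 11.04 to 3.09 ± 1.36 CPM (−3.21, SE 0.38, adjusted p = 0.000689), and Pdgfc, a platelet-derived growth factor, by 2.92 on the log2 scale. This list had 5 falling members without LFA1-hi replicate 1 and 3 rising without LFA1-lo replicate 3. It had camera adjusted p = 0.0377, and adjusted p = 0.253 with an estimated correlation (alternatives from 0.0095), and was lost at the 10 CPM filter, with limma voom and on TPM or FPKM.

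Of 28 genes of the matrix and its remodelling 10 fell (11 adjusted over the list alone) and 5 rose (median −0.26), while the summed level was 10920 CPM in LFA1-lo and 14000 CPM in LFA1-hi. Thbs1, encoding thrombospondin 1, fell from 149 ± 37.7 to 13.5 ± 3.74 CPM (−3.47, SE 0.27, edgeR adjusted p = 0.000155), and Col4a1 (−3.50) and Col4a2 (−3.75), the chains of collagen IV, fell from lower levels. Rising members numbered 3 and 2 without LFA1-hi replicates 2 and 3. Camera gave this list adjusted p = 0.0478, and adjusted p = 0.529 with an estimated correlation. It was lost without LFA1-lo replicate 2 (adjusted p = 0.274) or LFA1-hi replicate 2 (adjusted p = 0.0644), at the 10 CPM filter (median turned to 0.06 over 19 members, adjusted p = 0.627), with limma voom, TPM or FPKM, and did not pass in fry, over alternatives of 0.0137 to 0.627. Of 13 osteoclast genes 6 fell and 1 rose, and the list did not pass (median −0.43, adjusted p = 0.0955). Dcstamp, needed for the fusion of osteoclast precursors (−4.63, adjusted p = 0.00803; −3.68 without LFA1-lo replicate 2), and the kinase gene Src (−2.43, adjusted p = 0.00161) fell, and Acp5, tartrate-resistant acid phosphatase, rose by 1.82. The list passed without LFA1-lo replicate 2 (adjusted p = 0.0362) or 3 (adjusted p = 0.0103, range over alternatives 0.0103 to 0.537). Falling members numbered 3 without LFA1-hi replicate 2 or 3, and rising members 2 without LFA1-lo replicate 2.

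Among 17 leukocyte integrins and partners 2 rose and 5 fell (median −0.06, list adjusted p = 0.598). Icam2 (1.55, SE 0.23, edgeR adjusted p = 0.000999) rose and Icam1 (−1.09, adjusted p = 0.000248) fell, both of them ligands of LFA1, and Itga6, a laminin receptor chain, fell by 0.55 on the log2 scale. Falling members numbered 2 without LFA1-lo replicate 1 or LFA1-hi replicate 2 or 3 and 3 without LFA1-hi replicate 1, and rising members 1 without LFA1-hi replicate 2 or 3. Of 30 cytoskeletal genes 7 rose and 8 fell (5 without LFA1-hi replicate 2; median −0.01, adjusted p = 0.629), with Ezr, which links membrane to actin, at 1.25 and Marcks, an actin regulator, at −0.92. Of 16 genes of alternative activation 3 rose and 4 fell (median −0.11, adjusted p = 0.601), among them Egr2 (−1.98). Here 5 rose and 9 fell without LFA1-lo replicate 2, none rose without LFA1-lo replicate 1, and 1 rose without LFA1-hi replicate 2 or 3.

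Of 25 antioxidant and iron genes 4 rose and 4 fell (median −0.06, adjusted p = 0.855), and Hmox1, the enzyme that breaks down haem, rose from 753 ± 158 to 1525 ± 144 CPM (1.02, SE 0.15, edgeR adjusted p = 0.0014). Falling members numbered 7 without LFA1-lo replicate 3 and 2 without LFA1-hi replicate 2 or 3. Of 28 heat shock and unfolded protein genes 8 rose and 3 fell (median 0.13, adjusted p = 0.408), including Sdf2l1, a chaperone cofactor of the endoplasmic reticulum (0.64, adjusted p = 0.00396). Without LFA1-lo replicate 2, 14 of them rose and the list passed (adjusted p = 0.0148, range over alternatives 0.0148 to 0.875). Rising members numbered 2 without LFA1-lo replicate 1 or LFA1-hi replicate 1 or 2 and 3 without LFA1-lo replicate 3 or LFA1-hi replicate 3, and falling members 1 without LFA1-lo replicate 1 or LFA1-hi replicate 2 or 3. Of 40 ribosomal protein genes 2 rose and 3 fell (adjusted over the list alone, 1 fell; median 0.04, adjusted p = 0.69), including Rpl10 (−0.38, adjusted p = 0.00395), and reads of their many pseudogenes leave single members uncertain. The balance depended on scaling, with 8 rising and 1 falling with library totals alone, 4 and 3 with upper-quartile factors and 9 and 1 on log2(FPKM + 0.1). In this list 9 rose without LFA1-lo replicate 2, none without LFA1-lo replicate 1 or any LFA1-hi library, and 1 fell without LFA1-lo replicate 1 or LFA1-hi replicate 2 or 3.

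Some list medians depended on the settings. Their sign turned in at least 1 alternative for integrins, B lymphocyte markers, chemokines, chemokine receptors, alternative activation, phagocytosis, cholesterol synthesis, antioxidant genes and the cytoskeleton, none of them called as lists. It also turned for the 2 mast cell, basophil and eosinophil markers, which had no set test. At the 10 CPM filter, which tests fewer genes, it turned for the matrix list, which was called (0.06), for megakaryocyte markers (0.08) and for the single progenitor marker left (0.88), and without a filter for stromal markers (−0.46). Erythroid markers, of which Tfrc alone was tested, had medians of −0.54 and −0.78 over 2 members without LFA1-lo replicates 2 and 3 and of −2.41, −2.07 and −1.48 over 3 without LFA1-hi replicates 1, 2 and 3. At the 10 CPM filter 3 monocyte genes, 2 chemokines, 2 genes of alternative activation and 5 growth factors fell. On log2(FPKM + 0.1) medians were nearer 0 for lysosomal genes (−0.12), pattern recognition receptors (−0.14), monocyte genes (−0.18) and the matrix (−0.17). Without LFA1-lo replicate 2 they were 0.42 for glycolysis, 0.22 for heat shock genes, −0.29 for osteoclast genes, −0.13 for the matrix and −0.82 for progenitor markers.

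Over all lists together, 679 of 870 genes were tested, and 360 of these passed over all genes, 185 higher and 175 lower in LFA1-hi, against 384 adjusted over the lists alone. Where no second count is given, a list had the same counts adjusted over the list alone. Of 37 lists tested by camera with the preset correlation of 0.01, 19 passed, 5 up and 14 down. With an estimated correlation camera called 0 (lowest adjusted p = 0.157), 6 had an unadjusted p under 0.05, and fry called 22.

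**Figure D3:**
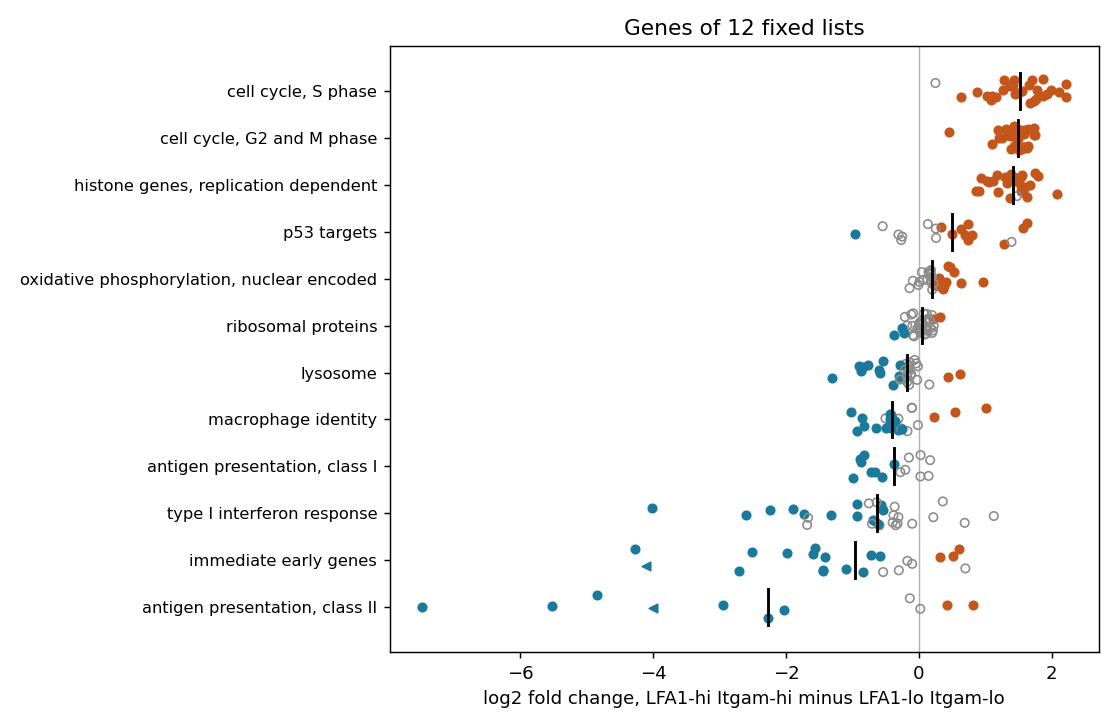
Log2 fold changes (LFA1-hi minus LFA1-lo) of the tested members of 12 gene lists, filled where a gene passed a false discovery rate of 0.05, open where it did not, with a black bar at each list's median and left-pointing triangles for genes with 0 counts in LFA1-hi, drawn at their lower bound. The cell cycle and histone medians lie at 1.41 to 1.52, the immediate early median at −0.97 and the class II median at −2.27.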

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

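Counts of list members without each library and the removal of GC and length trends were chosen after the results were seen. None of the 3705 called genes was called in the opposite direction under any alternative for which calls were compared gene by gene, which leaves out the removal of GC and length trends. The number of genes past the threshold (3705) ran from 2288 to 5032 over fits without a library, and those higher from 1169 to 2589 and lower from 1099 to 2443, with fewer samples in each fit. The highest of these values, 5032, 2589 and 2443, were those without LFA1-lo replicate 2. It was 2024 (1007 higher, 1017 lower) at a threshold of 0.01 and 832 (481 higher, 351 lower) against a 1.5-fold change, both stricter by construction. Other scalings gave 3702 to 3765, filters 3293 to 3593, and DESeq2 4052, limma voom 3742 and TPM or FPKM 3441 to 3662. The number of genes with the 95% interval within 1.5-fold (4844) became 8147 with a bound of 2-fold, wider by construction. Lists past the threshold (19) numbered 12 on log2(TPM + 0.1), and the cause was not tested. In camera with an estimated correlation they numbered 0 (6 at an unadjusted p under 0.05), while fry called 22. Estimated correlations were 0.309, 0.85 and 0.606 for S phase, G2 and M phase and histones. For inflammatory genes, pattern recognition receptors and complement they were 0.013, 0.012 and 0.011, near the preset 0.01, yet these lists were lost too. A higher correlation among their own genes thus does not account for their loss, and other causes were not tested. The first principal component held 62.2% with all genes, 61.7% with a prior count of 0.5, 82% on log2(TPM + 1), 69.5% with RLE factors and 64.7% to 71.7% without a library, and the cause of these shifts was not tested. Apart from the threshold of 0.01, the 1.5-fold test and the fits that are not robust, which were not counted here, lists stayed on their side of the threshold, called or not, in 677 cases, gained a call in 11 and lost it in 50, fry included. Lists were not tested with DESeq2, and after removal of GC and length trends only the 3 cell cycle and histone lists were. Named genes, not run without those trends, stayed on their side in 3083 cases, gained a call in 8 and lost it in 144.

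Libraries with the same replicate number did not deviate together (correlations of 0.037, 0.018 and −0.072 across genes), and not every library correlated best with its own number, so the numbers were not taken as pairs. With a replicate block 3253 genes passed (1692 higher, 1561 lower), 3161 of them among the 3705, and 20 lists, osteoclast genes being the added list (adjusted p = 0.0468). In that fit 6 interferon and 5 class II genes fell, and the calls of Cd74 (−4.35, adjusted p = 0.0602), Ifit3 (−2.44, adjusted p = 0.0612) and Siglecf (1.42, adjusted p = 0.0528) were not made.

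At a count of 3, or 0.170 to 0.198 CPM, the depth limits what can be seen of scarce transcripts. On simulated data 25% of 1.5-fold and 73% of 2-fold changes were recovered. Few genes were changed there (106 calls against 3705 here), which makes the adjusted threshold stricter, so these shares are not those of the real test. A gene that did not pass may still differ by such amounts, unless its 95% interval lay within 1.5-fold, as for 4844 genes, called or not.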

Other observations

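All tests in this part were chosen after the results they weigh were seen, and the genes of the first paragraph after their values were seen.

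Relb, a transcription factor of noncanonical NF-kB signalling, fell from 39.3 to 9.498 CPM in LFA1-hi macrophages (log2 fold change −2.05, SE 0.16, edgeR adjusted p = 4.77e-05), and Nfkb2, which encodes the partner of Relb, from 88.5 to 31.1 CPM (−1.51, SE 0.10, adjusted p = 2.62e-05). Birc3, an inhibitor of cell death, fell by 1.80 and Traf1, a signalling adaptor, by 1.73 on the log2 scale (adjusted p = 1.42e-05 and 0.00181). Plxdc2, a receptor of the cell surface, fell from 55.99 to 2.56 CPM (−4.44, adjusted p = 1.99e-05). Padi4, which converts arginine of histones to citrulline, rose from 5.09 to 36.3 CPM (2.83, SE 0.17, adjusted p = 1.42e-05) and Dach1, a transcription factor, from 2.82 to 21.1 CPM (2.90, SE 0.16, adjusted p = 9.81e-06). Trem1, an amplifier of inflammatory signals, rose by 2.97 (adjusted p = 0.000947; 3.81 without LFA1-lo replicate 1).

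The count of 3705 genes between the groups was set against the other splits of the 6 libraries into 3 and 3. Of the 10 splits, 1, the real grouping, gave as many genes, and the others gave 0 in edgeR, with 84 to 403 genes at an unadjusted p under 0.05 against 4987. Every other split mixes libraries of both groups, so the difference between the groups adds to the spread within each side and hinders calls. With 10 splits no share under 0.05 can be reached, so nothing is concluded from them.

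The cell cycle and histone genes were higher in LFA1-hi macrophages. A scaling factor moves all genes alike, whereas the lowest median of the 3 lists lay 1.42 above that of all tested genes (lower quartile 1.19), which argues against scaling as the cause of that difference. After removal of each library's trend over GC content and transcript length the lowest median was 1.06 (histones, from 1.44), with 26 of 28 histone, 27 of 28 S phase and 29 of 30 G2 and M phase genes still past the threshold, which argues against such a trend as the whole cause. Dividing progenitors in the LFA1-hi cultures could not be settled. Summed progenitor and primary granule transcripts were at 35.4 ± 4.3 CPM in LFA1-hi and 41.0 ± 3.9 CPM in LFA1-lo. These ranges overlap (up to 38.8 and down to 36.7), and whether the sort before the culture kept such cells out was not measured. A difference between the sorted subsets themselves stays open, untested.

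The class II antigen presentation genes were lower in LFA1-hi macrophages. LFA1-lo replicate 2 had the highest class II levels. Without it 7 members, the costimulatory gene Cd86 among them, still passed as lower (median −1.87), which argues against that library as the sole source. Dendritic cells in the LFA1-lo cultures could not be settled, since 6 of their markers had 68 counts over the 6 libraries, too few to weigh. Their sum was 0.894 ± 0.675 CPM in LFA1-lo and 0.484 ± 0.358 CPM in LFA1-hi. The sort came before the 7 days of culture, and whether it kept such cells out was not measured. A difference between the sorted subsets themselves stays open, untested.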
